A study of Mus musculus with 9 samples.

How the data were processed

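Messenger RNA was sequenced from CD133-positive kidney cells of mouse embryos in 9 libraries. The labels place 3 libraries in each of 3 groups: control with vehicle, Tsc1 mutant with vehicle and Tsc1 mutant with rapamycin. Per the labels' protocols, minced kidneys were digested with collagenase and dispase, stained for CD133 and sorted, RNA was extracted with Trizol, and a stranded mRNA kit was used with an Illumina NextSeq instrument. The labels name each replicate only by a number. Nothing in them says whether replicates are single embryos, litters or pools. RNA of the inactive X chromosome and of the Y chromosome occurred together in 8 of the 9 libraries. Those 8 thus held cells of both sexes, and so of more than 1 embryo. The p-values measure the spread between these libraries, which may be partly technical. Groups were taken from the sample labels alone.

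Per the submitters' processing notes, the tools were cutadapt 1.18, TopHat2 2.1.1, HTSeq 0.6.0 and DESeq2 1.22.1, on the mouse genome build GRCm38. The roles and options of these tools, the annotation release and whether counting used strand are not given in the sources used here. The authors deposited one table of 54838 genes that holds raw read counts, normalized counts, and their own log2 fold changes and p-values for each pair of groups. Raw counts were present for 48586 genes, and 6252 genes carried a mark in place of a count. A normalized count was present for 24539 genes, those with at least 10 raw counts over the 9 libraries. Each deposited normalized count equals the raw count divided by one size factor per library, with a largest relative departure of 5.3e-15, and the factors ranged from 0.874 to 1.19. Of 54809 gene identifiers shared with GENCODE M21, 98.75% had the same coordinates in both, and the coordinates printed here are those of the deposited table. The deposited values in their own unit are read counts and scaled counts, with no score or percent scale, and the authors' comparisons were used only where the text names the authors' deposited table.

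Total counts ranged from 23372093 to 32669791 per library, with 25808 to 27006 genes counted at least once. Any 2 libraries of one group differed by far more than sampling noise, since the lowest chi-square per degree of freedom was 17.2. Reads are not independent molecules, so intervals made from counts cover counting error only. Reads on genes that overlap ribosomal RNA made up 8.1% of control 1 and 4.79% of mutant rapamycin 2, and between 0.537% and 1.61% of the other libraries.

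Raw counts were divided by the authors' size factors and tested as log2(value + 1) with limma 3.58.1 (trended and robust variance, statmod 1.5.0) in R 4.3.3. Genes with a mean normalized count of at least 5 were tested, which left 19656. All 9 libraries entered one fit of 3 group means, so the groups share one estimate of spread, and no replicate block was used. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes on this scale understate the change of genes with few counts. The design fixed before the data were examined named edgeR's quasi-likelihood test first and this limma test for values that are not counts. The limma test was used because the mark for missing counts kept the columns from being accepted as counts, so edgeR was not run here.

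Gene lists were tested with camera, which compares the members of a list with all other genes, at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests the list alone. P-values were adjusted over the 29 lists of a comparison. The lists were fixed before the data were examined and covered mature proximal tubule function, nephron progenitors, committed nephron, podocytes, loop of Henle and distal tubule, ureteric bud and collecting duct, stroma, endothelium, leukocytes, erythroid cells, mTORC1 components, glycolysis and hypoxia, cholesterol and fatty acid synthesis, pentose phosphate and nucleotide synthesis, the ATF4 amino acid response, lysosome and TFEB targets, fatty acid oxidation, nuclear and mitochondrial oxidative phosphorylation genes, ribosomal proteins, ribosome biogenesis, cell cycle, cystic disease and cilia, tubule injury, interferon, dissociation and immediate early genes, glucocorticoid response, sex-linked genes and 6 checks. A further 5 lists (intercalated cell, principal cell, ureteric tip and trunk, abundant skeletal muscle, myogenic factors) were written after the calls had been seen.

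Genes were named by a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls per main comparison among called genes with a mean of at least 5 and no overlap between the 3 libraries of each group, leaving out predicted and sex-linked genes. It added up to 3 called members of each list that passed camera or had at least 3 called members, and otherwise allowed the member with the smallest p. Tsc1, Tsc2, Six2, Six3, Prom1, Fkbp1a and the sex-linked genes were always named. For treated mutants against controls it took 3 genes per direction, and for opposite calls 5 per direction.

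The tests were checked on simulated data, with counts drawn for the real genes and 200 genes changed. At a true fold of 2, 59.1% of changed genes were recovered for mutant against control over 19665 genes, 55.4% for rapamycin against vehicle over 19612 genes, and 56.1% for treated mutant against control over 19680 genes. At a fold of 1.5 the shares were 13.4%, 20% and 12.3%, and at a fold of 4 they were 78.1%, 81.5% and 82.5%. Of 105, 107 and 102 calls, 7, 5 and 5 were false. Overlaps between comparisons that share libraries were set beside 20 simulated draws of unchanged groups and beside the number that independent lists would share. In each draw the genes with the smallest p were taken, as many as were called in the data, whether or not they passed the test.

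Replicate numbers recur in the 3 groups. Deviations from the group mean were correlated across genes between libraries of the same number. Control and mutant vehicle libraries of the same number correlated at 0.43, 0.14 and 0.45, so these numbers were treated as pairing these libraries, and the value with this block is printed beside a result of mutant against control vehicle libraries where it changed the call or moved the count by more than 1.5 times. The rapamycin libraries were not paired with either group by the same check. Control and mutant vehicle libraries of unlike number correlated at -0.45 to 0.065. Control 1 and mutant rapamycin 2, the 2 libraries with the most ribosomal-overlap reads, correlated at 0.47, and control 3 and mutant rapamycin 1 at 0.39. Values this large thus occur without a shared number, so the pairing is an assumption. It comes from these values and not from the labels. Genes are not independent replicates in these correlations.

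The alternatives fixed beforehand and run were pseudocounts of 0.1 and 10, no filter on low values, a mean of at least 50, at least 5 CPM in 3 libraries, only the groups compared, the replicate number as a block, the other list tests, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the raw counts, scaling by the trimmed mean of M values and by library total, a replicate block in the control and mutant vehicle libraries only, and leaving out control 1 and mutant rapamycin 2 together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures. Dexamethasone, named in the title of the series, is in no sample label used here and was not analysed here.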

Results

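RNA was sequenced from cells of embryonic mouse kidneys sorted for CD133 (prominin-1, gene Prom1), a surface protein of proximal tubule and other epithelial cells, and named proximal tubule cells in the labels. The 9 libraries fall into 3 groups of 3. Control kidneys carried floxed alleles of Tsc1 and no Cre, although the sample titles call them wild type. Mutant kidneys also carried a Six2 Cre transgene, which is active in nephron progenitors. Tsc1 encodes hamartin, which with tuberin (Tsc2) holds back the growth-promoting kinase complex mTORC1. Pregnant dams received vehicle, or rapamycin, an inhibitor of mTORC1, at 0.2 mg/kg every other day from embryonic day E12.5 to E16.5, and kidneys were taken at E18.5. Treated controls are not among the groups analysed here. Library totals ranged from 23372093 to 32669791 counts. RNA of Xist, expressed from the inactive X chromosome, and of Y-linked genes occurred together in 8 of the 9 libraries. Control 1 was the exception, with 0 counts of Ddx3y and 14 Y-linked counts. The 8 libraries thus held cells of both sexes, and control 1 almost only female cells, so the mix of sexes differed between libraries.

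The first comparison asked what differed in the sorted cells when Tsc1 was deleted in the Six2 lineage. The targeted gene, Tsc1 (ENSMUSG00000026812, chromosome 2, 28641228 to 28691167, GRCm38), had 2041, 1744 and 1439.5 normalized counts in the controls. It had 1569.9, 1747 and 1624 in the mutant vehicle libraries and 1539, 1686 and 1526 in the mutant rapamycin libraries. Its log2 fold change between mutant and control vehicle libraries was -0.07 ± 0.13 (SE, n = 3 per group, limma adjusted p = 0.962). The fitted value was 0.05 without control 1. The deleted exons are not given in the sources used here, so a count over the whole gene does not check the deletion. Six2, the transcription factor of nephron progenitors whose promoter drives the Cre, rose in the mutants by 1.59 ± 0.13 log2, from 1109 ± 58.7 to 3355 ± 479.5 normalized counts (SD, n = 3, adjusted p = 0.000211). Neither Tsc2 (0.13, adjusted p = 0.848), Prom1 (0.17, adjusted p = 0.758) nor Fkbp1a, which encodes the binding partner of rapamycin (-0.12, adjusted p = 0.894), passed the test. Of these 6 checks, Six2 and Six3 made up the 2 that rose, and adjusted over the list alone the count was also 2 (adjusted p = 0.129 with an estimated correlation).

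The largest rise in the mutants was that of Six3 (ENSMUSG00000038805, chromosome 17, 85613608 to 85629302), a homeobox gene of forebrain and eye development. It went from 1.95 ± 0.954 to 889 ± 20.9 normalized counts (SD, n = 3), a log2 fold change of 8.29 ± 0.25 (SE, adjusted p = 3.83e-08). The raw counts were 6 in the controls and 2579 in the mutants, a ratio of 461 with an exact 95% counting interval of 212 to 1260. Six3os1, which overlaps Six3 on the other strand, rose by 4.45 ± 0.36 log2. Because the strand setting of the counting is not given, reads of these overlapping genes may not be separated, and the value of Six3os1 is uncertain. Rises were also called for Sectm1b, a secreted and transmembrane protein (5.52 ± 0.44), Ocm, the calcium-binding oncomodulin (5.17 ± 0.39), Matn1, a cartilage matrix protein (4.96 ± 0.47), and Srd5a2, a steroid 5-alpha reductase (4.02 ± 0.51). Matn1 rested on 3 counts in the controls (ratio 61.2, 95% 20.6 to 300) and Srd5a2 on 1 (ratio 62.3, 95% 10.7 to 2500). These rises of 6 genes passed the test in each of the 9 fits that left out 1 library.

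The largest falls included Hsd3b6, an enzyme of steroid synthesis, which fell by 4.70 ± 0.44 log2 (adjusted p = 0.000334). It had 99 counts in the controls and 1 in the mutants, a ratio of 92.2 with a 95% interval of 16.2 to 3680. Slc26a4, the chloride and bicarbonate exchanger pendrin, fell by 3.17 ± 0.30 from 89.9 ± 15.4 to 9.01 ± 1.06 normalized counts (SD, n = 3). Kap, an androgen-regulated gene of the proximal tubule, fell by 4.20 ± 0.89 (adjusted p = 0.0477), and Serpina6, the corticosteroid-binding globulin, fell by 3.35 ± 0.62. Tldc2 fell by 3.28 ± 0.67 and the homeobox gene Hmx2 fell by 3.17 ± 0.64. Tldc2 rested on 2 counts in the mutants (control to mutant ratio 21.4, 95% 5.6 to 182). Hsd3b6 and Slc26a4 kept their calls in all 9 fits that left out 1 library. Serpina6 lost its call without control 2, control 3 or mutant 2 (adjusted p up to 0.134), Kap in all but the fit without control 1 (up to 0.224), and Hmx2 in all but those without control 1 or mutant 3 (up to 0.171). Tldc2 was called in 1 of the 7 such fits that tested it (adjusted p up to 0.132).

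**Figure D1:**
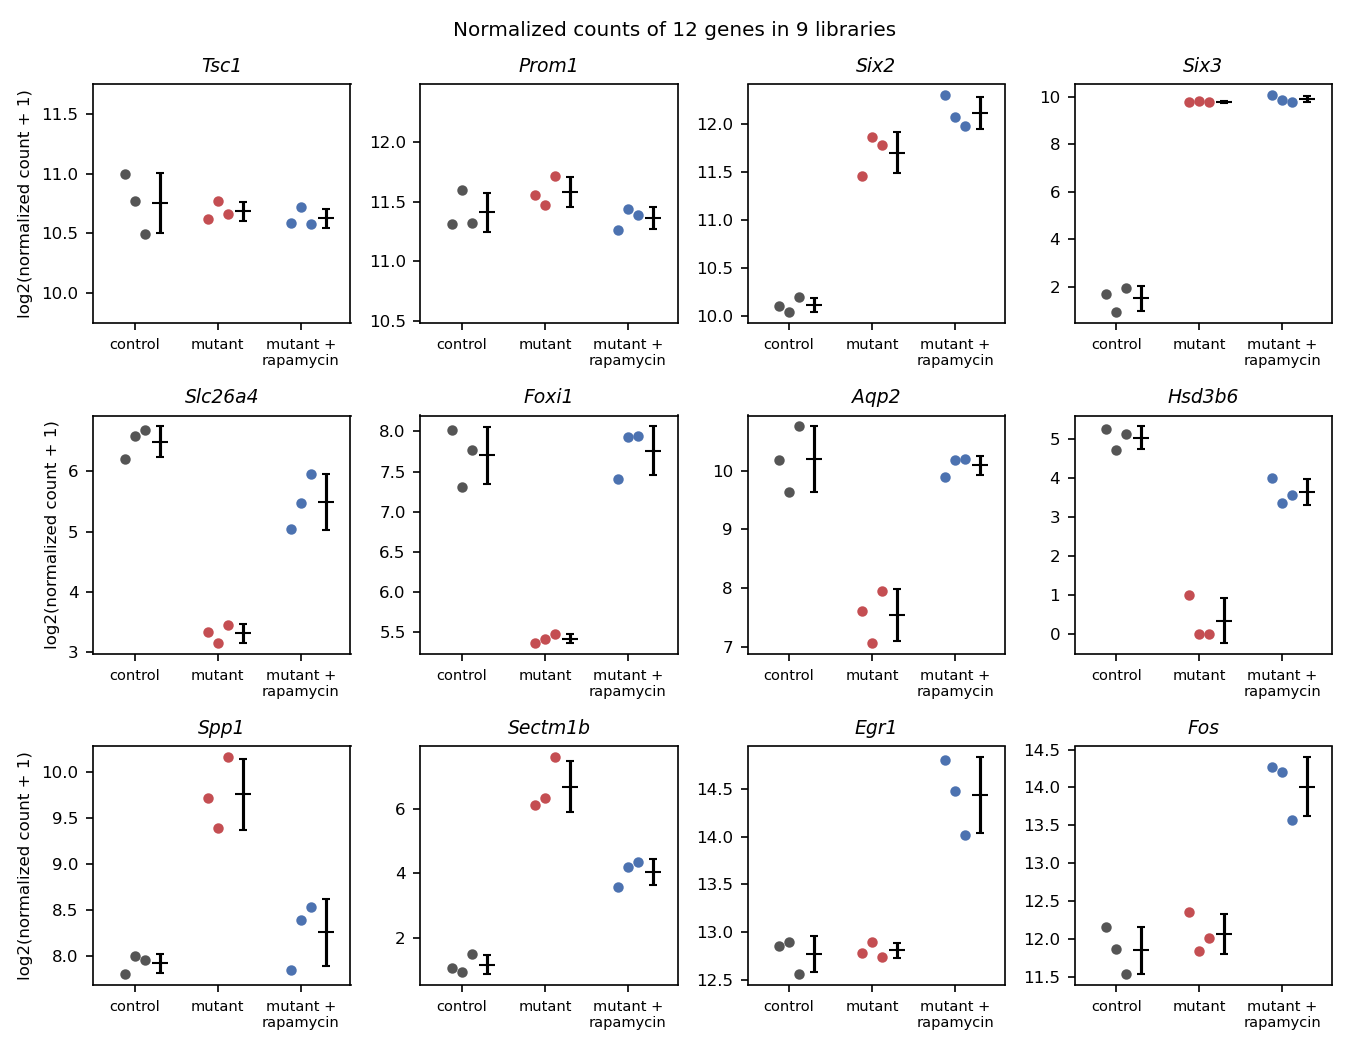
Normalized counts, as log2(value + 1), of 12 genes in control, mutant and mutant rapamycin libraries. Each point is 1 library, and the bar beside each group gives its mean and SD (n = 3). Six3 lies between 875 and 1074 normalized counts in the 6 mutant libraries and at or below 2.8 in the 3 controls.

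Genes of mature proximal tubule function moved in both directions in the mutants. Of 49 measured members, 7 rose and 4 fell, and adjusted over the list alone 16 rose and 6 fell (adjusted p = 0.485 with an estimated correlation). Ass1, which makes argininosuccinate (1.55 ± 0.13), Slc2a2, the glucose transporter GLUT2 (1.53 ± 0.16), and Gatm, the first enzyme of creatine synthesis (1.04 ± 0.14), rose and kept their calls in all 9 fits that left out 1 library. The count of 11 changed members was 5 without control 2, 6 without control 3, 4 without mutant 2, 7 without mutant 3, and 7 without rapamycin 1 or rapamycin 3. It was 20 with the replicate block in these groups. Of 31 measured genes of tubule injury and repair, 3 rose and 1 fell, and adjusted over the list alone 4 rose and 5 fell (adjusted p = 0.98 with an estimated correlation). Its median log2 fold change was -0.08 while its mean was 0.04 and its test pointed up. Spp1, encoding osteopontin, rose by 1.83 ± 0.22, Cd44, the hyaluronan receptor, by 0.98 ± 0.18, and Cdkn1a, the cell cycle inhibitor p21, by 0.93 ± 0.17. That count of 4 was 1 without control 2 or mutant 2, 2 without control 3 or rapamycin 3, and 7 with the block. Cd44 lost its call without control 2, control 3 or mutant 2 (adjusted p up to 0.115), and Cdkn1a without control 1, control 2, mutant 2, mutant 3 or rapamycin 3 (up to 0.125).

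Nephron progenitor genes other than Six2 shared its direction in part. Of 17 members, 5 rose and 1 fell, and adjusted over the list alone 8 rose and 2 fell (adjusted p = 0.158 with an estimated correlation). Crym, a thyroid hormone binding protein, rose by 2.15 ± 0.17 and Eya1, a cofactor of sine oculis homeobox proteins, by 1.66 ± 0.15, while the homeobox gene Meox2 fell by 1.95 ± 0.26, each in all 9 fits that left out 1 library. The count of 6 was 3 without control 2 or mutant 2. All 19 genes of the committed nephron and renal vesicle had a negative log2 fold change, with a median of -0.38. Only Dkk1, a Wnt antagonist, fell past the test (by 1.01 ± 0.19, adjusted p = 0.0271), and 9 fell adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). Dkk1 lost its call without control 1, control 2, mutant 2 or mutant 3 (adjusted p up to 0.15). The committed nephron count of 1 was 0 without control 2, mutant 2 or mutant 3, 2 without control 1, and 4 with the block.

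Collecting duct genes fell in the mutant libraries, and whether the cells expressing them had lost Tsc1 was not measured. Of 22 genes of the ureteric bud and collecting duct, 7 fell and 0 rose, and adjusted over the list alone 10 fell (adjusted p = 0.158 with an estimated correlation). The water channel Aqp2 fell by 2.65 ± 0.28 log2, from 1230 ± 470.8 to 190.9 ± 57 normalized counts (SD, n = 3), the water channel Aqp3 by 1.72 ± 0.26, and the transcription factor Elf5 by 1.62 ± 0.24. The count of 7 was 4 without control 1, control 3 or rapamycin 3, 2 without control 2, 1 without mutant 2, 4 without both control 1 and rapamycin 2, and 11 with the block. Aqp3 lost its call without mutant 2 (adjusted p = 0.0604), and Elf5 without control 2 or mutant 2 (up to 0.0604). In the loop of Henle and distal tubule, 2 of 20 genes fell, and adjusted over the list alone 1 rose and 5 fell (adjusted p = 0.609 with an estimated correlation). They were Cldn19, a tight junction protein of the thick ascending limb (fell by 1.27 ± 0.23), and Bsnd, a chloride channel subunit (by 1.40 ± 0.30). Cldn19 lost its call without control 2, control 3 or mutant 2 (adjusted p up to 0.133), and Bsnd in all fits but the one without mutant 3 (up to 0.179). The count of 2 was 0 by limma without control 2, control 3 or mutant 2 (6 to 8 at an unadjusted p under 0.05), 1 without mutant 1, rapamycin 2 or rapamycin 3, and with the block 3 fell and 1 rose. The test of this list at the preset correlation no longer passed with the block (adjusted p = 0.0649, against 0.017).

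Among genes tied to mTORC1 and amino acid supply, small numbers rose. Of 44 mTORC1 components, Flcn, encoding folliculin, rose by 0.75 ± 0.12, and Rragd, a Rag GTPase, by 0.70 ± 0.15. Adjusted over the list alone 4 rose (adjusted p = 0.158 with an estimated correlation). Of 50 lysosomal and TFEB target genes, 4 rose, and adjusted over the list alone 19 rose and 1 fell (adjusted p = 0.158 with an estimated correlation). Named members were the sialidase Neu1 (0.87 ± 0.15), the peptidase Tpp1 (0.63 ± 0.11) and the hexosaminidase Hexa (0.79 ± 0.15). Of 37 genes of the ATF4 response, 3 rose, and adjusted over the list alone 9 rose (adjusted p = 0.288 with an estimated correlation). They were the amino acid transporter Slc7a3 (2.04 ± 0.26), asparagine synthetase Asns (1.13 ± 0.17) and the glutathione-degrading Chac1 (2.83 ± 0.56). The lysosomal count of 4 was 0 without control 2, mutant 2 or mutant 3, 1 without rapamycin 3, 1 without both control 1 and rapamycin 2, and 9 without mutant 1, and with the block 16 rose and 1 fell. The ATF4 count of 3 was 1 without control 2, 5 without mutant 1, and 12 with the block. The mTORC1 count of 2 was 0 by limma without control 2 or mutant 2 (6 at an unadjusted p under 0.05 in each), 1 without any other 1 library except rapamycin 1, and 5 with the block. Slc7a3 kept its call in all 9 fits that left out 1 library. Flcn lost it without control 2 or mutant 2 (adjusted p up to 0.0682), Asns without control 2 (0.0592), and Neu1 without control 2, mutant 2 or mutant 3 (up to 0.106). Tpp1 lost it without control 2, control 3, mutant 2, mutant 3 or rapamycin 3 (up to 0.114), and Hexa without control 2, mutant 2, mutant 3, rapamycin 1 or rapamycin 3 (up to 0.133). Rragd lost it in all fits but the one without rapamycin 1 (up to 0.129), and Chac1 in all but the one without mutant 1 (up to 0.146).

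Proliferation and metabolism lists held few or no called genes. All 45 cell cycle genes had a negative log2 fold change (median -0.39). Of these, 0 were called by limma over all genes (27 at an unadjusted p under 0.05, 0 by limma-voom), and adjusted over the list alone 26 fell (adjusted p = 0.158 with an estimated correlation). The cell cycle count of 0 was 7 without mutant 1 and 15 with the block, and the glycolysis count of 1 was 0 by limma without control 2 (2 at an unadjusted p under 0.05) and 2 with the block. Ndrg1, a stress-induced gene, was the 1 of 32 glycolysis and hypoxia genes that rose (1.19 ± 0.18, lost without control 2, adjusted p = 0.0575), and 2 rose adjusted over the list alone (adjusted p = 0.886 with an estimated correlation). That list tested higher at the preset correlation without control 1 (adjusted p = 0.00268), mutant 2 (0.000115) or mutant 3 (0.0161), and lower without mutant 1 (0.0268), against 0.125 with all libraries. The 1 called gene of 40 in the cystic disease and cilia list was Six2, a progenitor gene, also 1 adjusted over the list alone, with a median of -0.03, a mean of 0.03 and a test that pointed up (adjusted p = 0.955 with an estimated correlation).

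No member was called by limma or by limma-voom in the lists that follow, and the count at an unadjusted p under 0.05 is given for each. It was 0 of 32 for cholesterol and fatty acid synthesis, where Elovl6 had the smallest p (0.22 ± 0.13, adjusted p = 0.673), 3 of 28 for pentose phosphate and nucleotide synthesis, and 0 of 75 for nuclear oxidative phosphorylation genes. It was 0 of 12 mitochondrially encoded genes, led by mt-Nd5 (0.32 ± 0.33, adjusted p = 0.884), 2 of 77 ribosomal protein genes, all of which had a negative log2 fold change, and 2 of 39 ribosome biogenesis genes. It was 12 of 31 interferon genes, all with a positive log2 fold change (median 0.42), 8 of 30 dissociation and immediate early genes, and 3 of 17 glucocorticoid response genes, led by Lcn2 (-1.24 ± 0.40, adjusted p = 0.24). Adjusted p-values with an estimated correlation were 0.955, 0.5, 0.665, 0.961, 0.497, 0.652, 0.158, 0.485 and 0.506 in that order, and adjusted over the list alone 2 immediate early genes rose and none of the others changed. Without control 1, limma called 1 ribosome biogenesis, 2 interferon and 1 immediate early gene, and with the block 1 ribosomal protein, 2 ribosome biogenesis, 2 interferon and 1 immediate early gene.

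Among markers of other cells, no gene was called by limma or limma-voom. At an unadjusted p under 0.05 there were 2 of 17 podocyte genes, led by Foxc2 (-0.51 ± 0.13, adjusted p = 0.103, and 0.0209 with the block), 6 of 22 stromal, 1 of 17 endothelial, led by Cldn5 (-0.52 ± 0.19, adjusted p = 0.309), 5 of 18 leukocyte and 1 of 7 erythroid genes. Adjusted over the list alone, 1 podocyte gene fell, 1 stromal gene rose and 2 fell, 1 leukocyte gene rose, 1 erythroid gene fell and no endothelial gene changed. Adjusted p-values with an estimated correlation were 0.961, 0.485, 0.961, 0.485 and 0.485 in that order. Of the 18 leukocyte genes 16 had a positive log2 fold change (median 0.50), the direction also of the lysosomal list. All 7 erythroid genes had a negative one (median -0.54). Without control 1, limma called 1 stromal and 1 leukocyte gene, without mutant 1 it called 1 podocyte, 1 stromal, 4 leukocyte and 1 erythroid gene, and with the block 1 podocyte, 3 stromal and 1 erythroid gene. Of 5 sex-linked genes none was called, and 0 had an unadjusted p under 0.05 (adjusted p = 0.485 with an estimated correlation). Log2 fold changes were 1.74 for Uty, 2.47 for Kdm5d, 3.26 for Ddx3y, 2.92 for Eif2s3y and -0.06 for Xist.

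In total 279 genes of 19656 were called between mutant and control vehicle libraries, 207 higher and 72 lower. Of these, 198 changed at least 2-fold, and 1990 genes had an unadjusted p under 0.05. Libraries of the 2 groups did not overlap for 13.3% of genes, where chance gives 10%. With the replicate block in these groups, 867 genes were called. The count was 96 without control 2, 168 without control 3, 81 without mutant 2, 139 without mutant 3 and 174 without rapamycin 3. The authors' deposited comparison passed 594 genes at an adjusted p of 0.05, and 277 of the 279 were among them. At the preset correlation of 0.01, 20 of the 29 lists passed, and with an estimated correlation 0 did, with a lowest adjusted p of 0.129. The number at the preset correlation was 16 to 20 with 1 library left out.

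The second comparison asked what rapamycin given to the dam changed in the sorted cells of mutant kidneys. The sort named in the labels used CD133, yet RNA of markers of other cells was plentiful. All 22 stromal, 17 endothelial, 18 leukocyte and 22 collecting duct list genes reached a mean of 5 normalized counts in controls. The stromal gene Col1a1 had 28756 to 65638 raw counts per library, against 2311 to 3442 for Prom1. Cells outside the Six2 lineage, with intact Tsc1, were thus probably included. Their share was not measured, and counts of different genes do not give it. Tsc1 (-0.06 ± 0.13, adjusted p = 0.929), Six3 (0.12 ± 0.25, adjusted p = 0.917) and Six2 (0.42 ± 0.13, adjusted p = 0.252) did not pass the test between treated and untreated mutants. Nor did Prom1 (-0.22, adjusted p = 0.52), Tsc2 (-0.09, adjusted p = 0.854) or Fkbp1a (0.16, adjusted p = 0.734). Of these 6 checks, 0 were called by limma and 0 by limma-voom, and 1 had an unadjusted p under 0.05. Collecting duct genes rose with rapamycin. Aqp2 rose by 2.55 ± 0.28 log2, from 190.9 ± 57 to 1095 ± 121 normalized counts (SD, n = 3), Aqp3 by 1.88 ± 0.26, and Scnn1g, the gamma subunit of the epithelial sodium channel, by 1.25 ± 0.19. Of 22 genes of the ureteric bud and collecting duct 6 rose, and adjusted over the list alone 12 rose (adjusted p = 0.139 with an estimated correlation). Foxi1, a transcription factor of intercalated cells of the collecting duct, rose by 2.34 ± 0.23, from 41.8 ± 1.61 to 218.6 ± 43.3 normalized counts, and Slc26a4 rose by 2.17 ± 0.30.

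The count of 6 collecting duct genes was 2 without control 2, 1 without mutant 2, 3 without rapamycin 1, 0 without rapamycin 2 (12 at an unadjusted p under 0.05) and 1 without rapamycin 3. It was 1 without both control 1 and rapamycin 2. Calls of Aqp2 and Foxi1 were lost only without rapamycin 2 (adjusted p = 0.0505), those of Aqp3 and Slc26a4 without mutant 2, rapamycin 2 or rapamycin 3 (up to 0.111 and 0.104), and that of Scnn1g also without control 2 (up to 0.172). Hsd3b6 rose by 3.30 ± 0.44, from 1 count to 36 in the group (ratio 34, 95% 5.72 to 1380), and lost its call without mutant 2, rapamycin 1, rapamycin 2 or rapamycin 3 (adjusted p up to 0.075). Klk1, tissue kallikrein, rose by 2.44 ± 0.38 and was the 1 called gene of 20 in the loop of Henle and distal tubule. Adjusted over the list alone 2 of these rose and 1 fell, with a median of -0.13, a mean of 0.08 and a test that pointed down (adjusted p = 0.984 with an estimated correlation). Klk1 lost its call without control 2, mutant 2, mutant 3, rapamycin 2 or rapamycin 3 (adjusted p up to 0.172).

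Immediate early genes, which cells switch on within minutes of a stimulus or of tissue dissociation, rose in the treated libraries. Of 30 genes of dissociation and immediate early response, 14 rose and 0 fell, and adjusted over the list alone 24 rose (adjusted p = 0.0693 with an estimated correlation). The transcription factor genes Fos, Egr1 and Nr4a1 rose by 1.94 ± 0.22, 1.63 ± 0.18 and 1.34 ± 0.14 log2. Normalized counts of Egr1 were 7178 ± 392.5 in untreated and 22670 ± 6008 in treated mutants (SD, n = 3), against 7026 ± 862 in controls. Arc, an immediate early gene best known in neurons, rose by 2.29 ± 0.25, and Cyr61, a matricellular protein in the injury list, by 1.94 ± 0.20. The count of 14 was 2 without mutant 2, 9 without rapamycin 1, 0 without rapamycin 2 (22 at an unadjusted p under 0.05), and 9 without both control 1 and rapamycin 2. Egr1, Nr4a1, Arc and Cyr61 lost their calls without rapamycin 2 (adjusted p = 0.0505), and Fos also without mutant 2 (up to 0.0526). Of 32 glycolysis and hypoxia genes 2 rose, and adjusted over the list alone 26 rose (median 1.07, adjusted p = 0.194 with an estimated correlation). The 2 were the oxygen-sensing hydroxylase Egln3 (1.21 ± 0.19) and the hexokinase Hk1 (0.60 ± 0.10). Of 22 stromal markers 1 rose, the collagen gene Col1a1 (0.76 ± 0.13), and adjusted over the list alone 12 rose (median 0.66, adjusted p = 0.0851 with an estimated correlation). The glycolysis count of 2 was 20 without mutant 1 and 0 without control 2, mutant 2, mutant 3 or any 1 of the rapamycin libraries, each by limma with 21 to 29 at an unadjusted p under 0.05. The stromal count of 1 was 4 without control 1 or control 3, 5 without mutant 1, and 0 without control 2, mutant 2, mutant 3 or any 1 of the rapamycin libraries (12 at an unadjusted p under 0.05 in each).

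The largest falls with rapamycin included Ddn, encoding dendrin, a protein of podocytes, the filtering cells of the glomerulus, which fell by 1.88 ± 0.30. Sprr1a, a cornified envelope protein, fell by 3.16 ± 0.47, and Sectm1b fell by 2.65 ± 0.44. Scgn, the calcium sensor secretagogin, fell by 1.96 ± 0.33, and Spp1 fell by 1.50 ± 0.22. Of 31 injury and repair genes, Cyr61 rose and Spp1 fell, and adjusted over the list alone 2 rose and 1 fell (adjusted p = 0.666 with an estimated correlation). Anpep, the brush border aminopeptidase N, was the 1 of 49 proximal tubule genes that rose (0.74 ± 0.11), and adjusted over the list alone 8 rose and 3 fell (adjusted p = 0.409 with an estimated correlation). The proximal tubule count of 1 was 4 without control 1, 2 without control 3, and 1 without mutant 1, where 1 other member fell. No member was called by limma in the other fits that left out 1 library (14 to 20 at an unadjusted p under 0.05). The injury count of 2 was 1 without control 2, mutant 2, mutant 3 or rapamycin 1 and 0 by limma without rapamycin 2 (7 at an unadjusted p under 0.05). Irs2, an insulin signalling adaptor, was the 1 of 44 mTORC1 components that rose (0.78 ± 0.14), also 1 adjusted over the list alone. That list had a median of -0.05, a mean of -0.01 and adjusted p = 0.901 with an estimated correlation. Calls of Ddn, Sectm1b, Scgn, Anpep, Irs2, Egln3, Hk1 and Col1a1 were lost without control 2, mutant 2, mutant 3, rapamycin 1, rapamycin 2 or rapamycin 3 (adjusted p up to 0.299). That of Spp1 was lost without control 2, mutant 2, mutant 3, rapamycin 1 or rapamycin 2 (up to 0.0952), and that of Sprr1a without mutant 2, mutant 3, rapamycin 1, rapamycin 2 or rapamycin 3 (up to 0.147).

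No member of the other lists was called between treated and untreated mutants by limma or limma-voom. Among 19 committed nephron genes 9 had an unadjusted p under 0.05 (median -0.32), as did 3 of 17 nephron progenitor genes, led by Osr1 (0.84 ± 0.21, adjusted p = 0.143), and 7 of 37 ATF4 response genes, led by Atf3 (0.98 ± 0.23, adjusted p = 0.125). Counts were 6 of 50 for lysosome and TFEB targets, 1 of 45 for cell cycle, led by Rrm2 (-0.47 ± 0.15, adjusted p = 0.231), 3 of 31 for interferon, led by Mx1 (-0.82 ± 0.25, adjusted p = 0.225), and 7 of 17 for glucocorticoid response. Adjusted p-values with an estimated correlation were 0.407, 0.409, 0.86, 0.742, 0.855, 0.901 and 0.0851 in that order. For endothelium, leukocytes, erythroid cells, ribosomal proteins, ribosome biogenesis, cholesterol and fatty acid synthesis, and cystic disease and cilia they were 0.32, 0.409, 0.561, 0.834, 0.837, 0.561 and 0.139. Members of these lists at an unadjusted p under 0.05 numbered 8 of 17, 5 of 18, 1 of 7, 1 of 77, 3 of 39, 9 of 32 and 4 of 40. For pentose phosphate and nucleotide synthesis, fatty acid oxidation, and nuclear and mitochondrial oxidative phosphorylation genes they were 0.901, 0.855, 0.86 and 0.855, and the counts at an unadjusted p under 0.05 were 3 of 28, 2 of 30, 0 of 75 and 0 of 12. Adjusted over the list alone, 4 committed nephron genes fell, 1 progenitor gene rose, 2 ATF4 genes rose and 1 fell, 1 lysosomal gene fell, 6 endothelial and 4 glucocorticoid response genes rose, and none changed in the other lists of this paragraph. With 1 library left out, limma called 1 endothelial, 1 ATF4 and 2 glucocorticoid response genes without control 1, 1 glucocorticoid response gene without control 2, and 2 leukocyte, 3 cholesterol and fatty acid synthesis, 1 ribosome biogenesis and 1 glucocorticoid response gene without mutant 1. Of the 5 sex-linked genes 0 were called and 0 had an unadjusted p under 0.05 (adjusted p = 0.86 with an estimated correlation).

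Between treated and untreated mutants 59 genes were called, 48 higher and 11 lower, of which 45 changed at least 2-fold, and 2302 had an unadjusted p under 0.05. Libraries of the 2 groups did not overlap for 18.4% of genes, where chance gives 10%. The number called was 0 without rapamycin 2 (1825 at an unadjusted p under 0.05), 200 without mutant 1, 108 without control 1, 33 without control 2, 7 without mutant 2, 25 without mutant 3, 22 without rapamycin 1 and 25 without rapamycin 3. It was 22 without both control 1 and rapamycin 2. None of the 26 named calls of this comparison held in all 9 fits that left out 1 library. The authors' deposited comparison passed 390 genes at an adjusted p of 0.05, and all 59 were among them. At the preset correlation 16 of 29 lists passed, and with an estimated correlation 0 did.

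**Figure D2:**
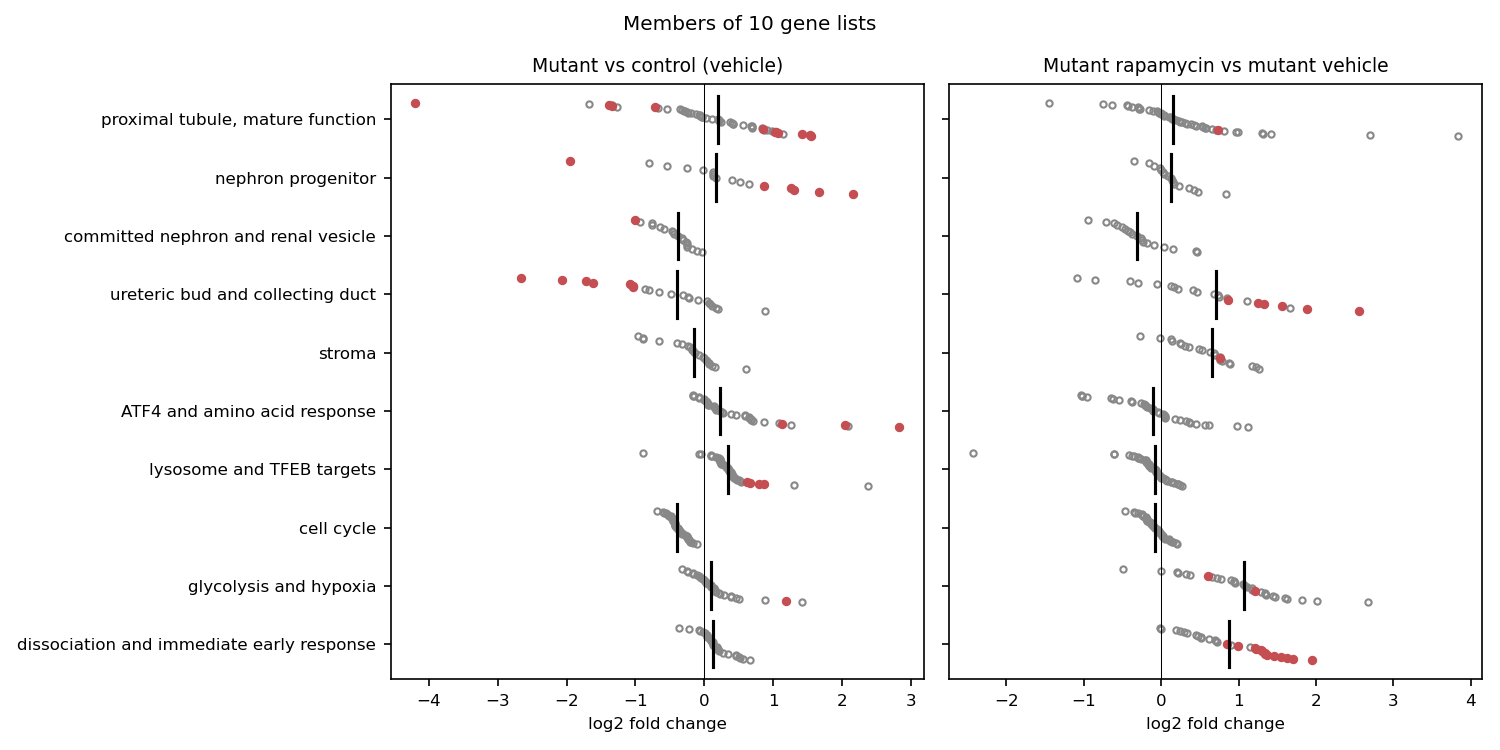
Log2 fold changes of the members of 10 gene lists between mutant and control vehicle libraries (left) and between treated and untreated mutants (right). Each circle is 1 gene, filled where its adjusted p is under 0.05, and the vertical bar is the list's median, which for glycolysis and hypoxia is 0.09 on the left and 1.07 on the right.

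Genes called in both comparisons all moved in opposite directions. In the mutants 6 genes rose that fell with rapamycin, and 15 fell that rose with rapamycin. Spp1, Sectm1b and Sprr1a were among the former, with Gpx3, the secreted glutathione peroxidase (2.50 ± 0.19, then -1.11 ± 0.19), and Scgn (3.04 ± 0.33, then -1.96 ± 0.33). Among the latter were Foxi1, Aqp2, Hsd3b6 and genes of intercalated cells, Slc4a9, an anion exchanger (-2.99 ± 0.22, then 1.95 ± 0.22), and Atp6v1b1, a proton pump subunit (-2.66 ± 0.24, then 2.05 ± 0.24). Aqp2 had 1230 ± 470.8, 190.9 ± 57 and 1095 ± 121 normalized counts in control, mutant and treated mutant libraries (SD, n = 3). Of the 207 genes higher in the mutants, 150 were still called higher against controls in the treated libraries, with a median log2 fold change of 1.35 in untreated mutants and -0.14 between treated and untreated mutants. Of the 72 lower genes, 18 were still called lower, with medians of -1.48 and 0.69.

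Both comparisons contain the mutant vehicle libraries, so genes ranked high in both tend to move in opposite directions by chance. The 21 opposite calls compare with 0.292 for independent lists. In simulated unchanged groups that share these libraries, on average 17.8 genes were in both top ranks (279 and 59) with opposite directions. These were taken by smallest p whether or not they passed the test, so 17.8 is not a number of calls expected by chance. The correlation across genes of the 2 log2 fold changes was -0.346, against -0.502 in the simulation, and the covariance was -0.0692, against -0.0592. With the 3 mutant libraries divided between the comparisons, 1 and 2 each, the covariance ranged from -0.0467 to 0.0636, with values of both signs. Across all genes, opposite movement beyond what the shared libraries bring was thus not shown. Genes are not independent replicates. The count of 21 was 0 without rapamycin 2 (a fit in which 0 genes were called for rapamycin and 1825 had an unadjusted p under 0.05), 47 without mutant 1, 8 without control 2, 3 without mutant 2, 10 without mutant 3, 7 without rapamycin 1 and 5 without rapamycin 3. It was 7 without both control 1 and rapamycin 2. With 1 library left out, Sprr1a was called against controls in 3 of 9 fits (adjusted p up to 0.151 without control 1, control 2, control 3, mutant 2, mutant 3 or rapamycin 2). The fall of Gpx3 with rapamycin lost its call without control 2, mutant 2, mutant 3, rapamycin 1, rapamycin 2 or rapamycin 3 (up to 0.256), the rise of Slc4a9 without rapamycin 2 (0.0505), and that of Atp6v1b1 without mutant 2 or rapamycin 2 (up to 0.0621).

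**Figure D3:**
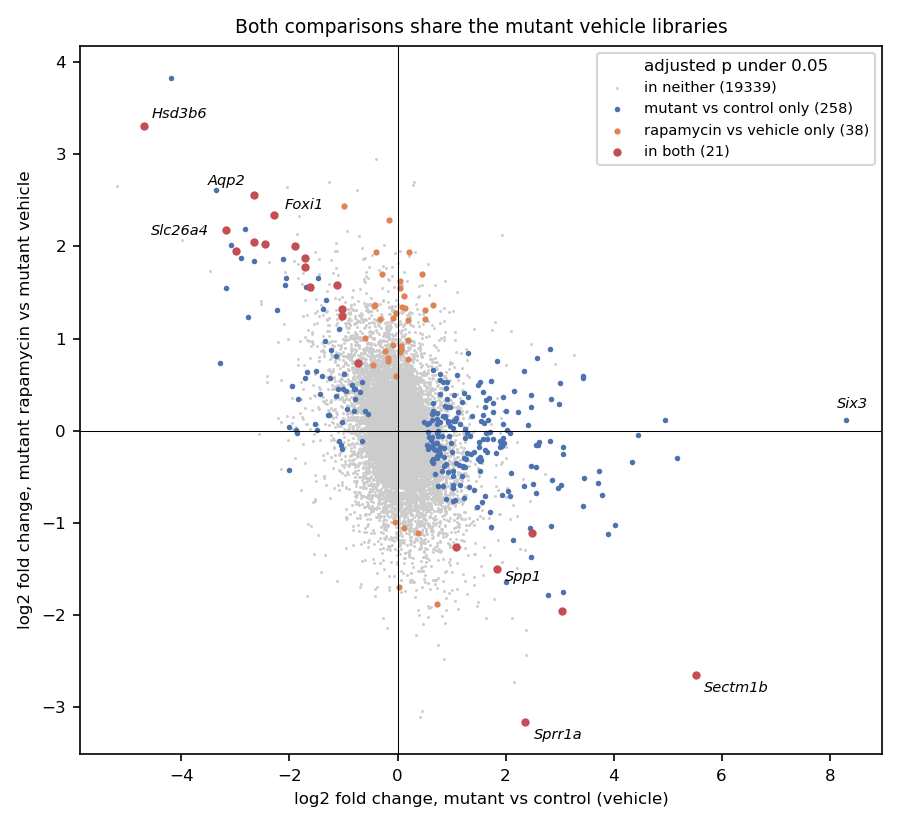
Log2 fold change of each of 19656 genes between mutant and control vehicle libraries (horizontal) and between treated and untreated mutants (vertical). Red points are the 21 genes called in both, blue the 258 called only in the former and orange the 38 called only in the latter, and the shared mutant vehicle libraries tilt the whole cloud.

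The last comparison set treated mutants against vehicle controls, which differ in genotype and drug at once. Six3 was higher by 8.41 ± 0.25 log2 (2957 counts against 6, ratio 499, 95% 229 to 1360), Matn1 by 5.07 ± 0.47 (193 counts against 3, ratio 65.2, 95% 22 to 319) and Ocm by 4.87 ± 0.39. Phex, which regulates phosphate balance, fell by 2.43 ± 0.35, from 286.9 ± 81.7 to 54 ± 21.4 normalized counts (SD, n = 3), Tnfrsf18, a receptor of the tumour necrosis factor family, fell by 2.68 ± 0.45, and Fam163a by 2.40 ± 0.50. Of 49 proximal tubule genes 12 rose, and adjusted over the list alone 14 rose (adjusted p = 0.141 with an estimated correlation). Of 19 committed nephron genes 8 fell, and adjusted over the list alone 12 fell (median -0.66, adjusted p = 0.0899 with an estimated correlation). Of 17 nephron progenitor genes 5 rose and 2 fell, and adjusted over the list alone 9 rose and 3 fell (adjusted p = 0.0899 with an estimated correlation). Of 30 immediate early genes 21 rose, and adjusted over the list alone 24 rose (adjusted p = 0.0899 with an estimated correlation). Of 22 collecting duct genes 2 rose and 0 fell, the same adjusted over the list alone (median 0.01, adjusted p = 0.755 with an estimated correlation). This count of 2 was 0 by limma without control 2 or rapamycin 1 (2 at an unadjusted p under 0.05 in each), and 1 without control 1, mutant 2, rapamycin 2, rapamycin 3 or both control 1 and rapamycin 2. For the 7 erythroid genes the median was 0.39 and the mean 0.13 while the test pointed down (adjusted p = 0.937 with an estimated correlation). Of 22 stromal markers 7 rose and 1 fell, and adjusted over the list alone 11 rose and 2 fell (adjusted p = 0.141 with an estimated correlation). Of 32 glycolysis and hypoxia genes 8 rose, and of 45 cell cycle genes 5 fell, with 28 and 36 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation for both). The stromal count of 8 was 0 without control 2, rapamycin 1 or rapamycin 2, 4 without control 3, 5 without mutant 2 or mutant 3, and 1 without rapamycin 3. The glycolysis count of 8 was 18 without control 1, 25 without mutant 1, 2 without control 2, 5 without rapamycin 1 and 4 without rapamycin 2 or rapamycin 3. The cell cycle count of 5 was 9 without control 1, 12 without mutant 1, 0 without control 2 or rapamycin 2, 2 without control 3 or rapamycin 1, 3 without mutant 2 or mutant 3, and 1 without rapamycin 3. Without both control 1 and rapamycin 2 these counts were 5, 4 and 1.

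Between these groups 637 genes were called, 452 higher and 185 lower, of which 342 changed at least 2-fold, and 3444 had an unadjusted p under 0.05. Libraries did not overlap for 23.1% of genes, where chance gives 10%. The count was 1131 without control 1, 175 without control 2, 359 without control 3, 388 without mutant 2, and 231, 216 and 252 without rapamycin 1, 2 and 3. The count of 12 proximal tubule genes was 4 without control 2, 6 without mutant 2, 3 without rapamycin 1, and 4 without rapamycin 2, rapamycin 3 or both control 1 and rapamycin 2. The count of 8 committed nephron genes was 4 without control 2, control 3 or any 1 of the rapamycin libraries and 5 without mutant 2, and that of 7 progenitor genes was 3 without control 2 or rapamycin 1 and 4 without rapamycin 3. Tnfrsf18 lost its call without control 2 (adjusted p = 0.0682), and Fam163a without control 2, control 3, mutant 2 or any 1 of the rapamycin libraries (up to 0.14). The authors' deposited comparison passed 1228 genes at an adjusted p of 0.05, and 630 of the 637 were among them. The same calls in this comparison and between mutant and control vehicle libraries numbered 168, against 5.44 for independent lists. In simulated unchanged groups, on average 74.5 genes were in both top ranks with the same direction. These were taken by smallest p whether or not they passed the test, so 74.5 is not a number of calls. The covariance of log2 fold changes was 0.138, against 0.0585 in the simulation. Part of the excess of 168 over independent lists may come from the shared control libraries.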

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

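Tests chosen only after the results were seen were limma-voom, scaling by the trimmed mean of M values or by library total, the block in control and mutant vehicle libraries only, and leaving out control 1 and mutant rapamycin 2 together. The 279 genes called between mutant and control became 185 with at least 5 CPM in 3 libraries, 99 with only the groups compared, 867 with that block (the 279 among them), and 81 (without mutant 2) to 336 (without mutant 1) with 1 library left out. The 59 genes called with rapamycin became 103 with no filter, 206 with the replicate block on all libraries, 22 without the 2 libraries with the most ribosomal-overlap reads, and 0 (limma without rapamycin 2, where 1825 had an unadjusted p under 0.05) to 200 (without mutant 1). The 637 genes between treated mutants and controls became 1090 with the replicate block and 175 (without control 2) to 1131 (without control 1). With the block in control and mutant vehicle libraries only, the counts in the comparisons with the unpaired rapamycin libraries were 883 in place of 59 and 2440 in place of 637. By its construction that block takes the spread between pairs out of the error but not out of the mean of the group compared with the rapamycin libraries, so these counts overstate the evidence. In mutant against control it changed the call of 1 fixed list at the preset correlation, loop of Henle, and of 1 named gene, Foxc2, and no other of these calls. The 21 opposite calls became 12 at 5 CPM, 39 with the replicate block, 7 without those 2 libraries, and 0 (without rapamycin 2) to 47 (without mutant 1). The 20, 16 and 23 lists called at the preset correlation became 0, 0 and 0 with an estimated correlation and 4, 4 and 13 by fry. In mutant against control fry passed nephron progenitor (adjusted p = 0.0126), mTORC1 (0.0346), lysosome (0.0414) and the checks (3.8e-06). With rapamycin against vehicle fry passed immediate early (adjusted p = 0.00337), stroma and glucocorticoid response (0.0103 for both) and collecting duct (0.0263). Fewer libraries or only 2 groups leave fewer degrees of freedom, and otherwise the cause was not tested. Pseudocounts, a mean of at least 50, limma-voom (241, 47 and 621 genes) and both other scalings (286, 75 and 637, or 279, 54 and 629) stayed within 1.5 times. Of 1639 values of named genes under alternatives, 1637 kept their direction and 272 no longer passed the test, and the other 2 were those of Tsc1, at 0.05 without control 1. Control and rapamycin libraries of the same number correlated at -0.34, -0.014 and 0.22 and mutant and rapamycin libraries at -0.13, 0.077 and 0.061, so no pairing with the rapamycin libraries was taken. The planned DESeq2 test and RLE size factors were not run. At a fold of 1.5 the self-test recovered 12.3% to 20% of changed genes, so changes of that size were mostly out of reach.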

Other observations

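All tests of explanations in this part except the splits of the libraries were chosen only after the result was seen. Genes of both cell types of the collecting duct fell in the mutants, by lists written after the calls were seen. Of 18 intercalated cell genes 10 fell, and adjusted over the list alone 15 fell (median -2.17, adjusted p = 0.00746 with an estimated correlation). Of 12 principal cell genes 6 fell, and adjusted over the list alone 8 fell (median -1.31, adjusted p = 0.00746 with an estimated correlation), but 7 of the 12 are also in another list. With rapamycin 4 of each rose, and adjusted over the list alone 13 and 9 rose (adjusted p = 0.0244 and 0.0103 with an estimated correlation). The lists were chosen on these samples, so they are not independent evidence of direction. Among genes of ureteric tip and trunk, 14 of them also in another list, 2 of 17 fell in the mutants (adjusted p = 0.402 with an estimated correlation). That count was 0 by limma without control 2, mutant 2, mutant 3 or any 1 of the rapamycin libraries (4 or 5 at an unadjusted p under 0.05), 1 without control 3 or mutant 1, and with the block 3 fell and 1 rose. In the mutants the intercalated count of 10 was 6 without control 2 or mutant 2, and the principal count of 6 was 2 without control 2 and 1 without mutant 2. With rapamycin the intercalated count of 4 was 2 without mutant 2 and 0 without rapamycin 2 (11 at an unadjusted p under 0.05). The principal count of 4 was 2 without control 2, 1 without mutant 2 or rapamycin 3, and 0 without rapamycin 2 (9 at an unadjusted p under 0.05).

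A few genes known from skeletal muscle, chosen after their values were seen, rose in both mutant groups against controls, while the test of a list of abundant skeletal muscle genes pointed up but did not pass. Actn3, a fast-fibre actinin, rose by 2.48 in untreated and 2.73 in treated mutants, and Atp2a1, the sarcoplasmic calcium pump, by 2.83 and 3.72. Mybpc1 (2.96 and 2.34) and Trim63 (2.56 and 2.17) rose as well, while Acta1, skeletal actin, had -0.92 and -0.13 and was not called. Of 13 abundant skeletal muscle genes 0 were called in untreated mutants by limma or limma-voom, with 4 at an unadjusted p under 0.05, and adjusted over the list alone 2 rose and 1 fell (median 0.31, adjusted p = 0.402 with an estimated correlation). In treated mutants 2 of the 13 rose, with a median of 0.02 (adjusted p = 0.982 with an estimated correlation), and 3 rose adjusted over the list alone. With the block in control and mutant vehicle libraries 1 of them fell in untreated mutants, and the count of 2 was 1 without rapamycin 1.

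Six3, Six3os1 and Six2 were higher in both mutant groups, and controls carry no Cre. If the Cre transgene brought extra copies of this region, its neighbours could be higher too. Of 3 measured genes that start within 200 kb of Six2 and overlap none of these, 3 were called higher in at least 1 mutant group. In untreated and treated mutants, AC166821.1 rose by 2.84 and 3.19 (adjusted p = 0.000269 and 0.000104) and Gm29418 by 1.96 and 1.88 (0.0465 and 0.0353). AC151289.1 was called only in treated mutants (2.01 and 2.72, adjusted p = 0.115 and 0.0195). Of 9 genes tested from 200 to 1000 kb away 1 was called higher, Slc3a1, a proximal tubule list member (0.99 in treated mutants, adjusted p = 0.0201). For Tsc1 loss acting through rapamycin-sensitive signalling at harvest, the log2 fold change of Six3 with rapamycin was 0.116 (95% -0.427 to 0.659). The last injection was at E16.5 and harvest at E18.5. Neither the lysosome and TFEB list nor the mTORC1 list passed with rapamycin by camera with an estimated correlation (adjusted p = 0.742 and 0.901). That test passed 0 of the 29 lists in this comparison, so failing it says little. By camera at the preset correlation the lysosome list was lower (adjusted p = 0.0125) and the mTORC1 list did not pass (0.863). Whether the drug acted at harvest is thus not settled, so the value of Six3 decides nothing. Transgene and Tsc1 loss are confounded in this design.

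Collecting duct genes were lower in untreated mutants. A lower share of all ureteric-lineage cells in the sort stays open. Intercalated and principal cell genes fell more than tip and trunk genes (mean difference -1.35, permutation p = 7e-05 over 47 genes), but these lists were written after the calls were seen, and some tip and trunk genes are also expressed in other cells. Among members of the collecting duct list fixed beforehand, 7 principal cell and 13 tip and trunk genes differed by -1.2 (permutation p = 0.0018), a division also made afterwards. A lower share of differentiated collecting duct cells stays open as well, with a difference between intercalated and principal cell genes of -0.565 (permutation p = 0.18 over 30 genes). Genes are not independent, so these p-values are too small if genes move together, and a change of expression within these cells cannot be told apart from such a share.

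Immediate early genes were higher in the rapamycin libraries. More stromal cells in the sort is not decided. Immediate early genes rose more than stromal markers (mean difference 0.324, permutation p = 0.023 over 52 genes). Genes are not independent, so this p-value is too small if genes move together. The immediate early minus stromal score was 0.225 to 0.493 in rapamycin and -0.111 to 0.182 in mutant vehicle libraries, a narrow gap. It was -0.369 to -0.315 in controls, so it also separated the 2 vehicle groups, between which no immediate early gene was called. Longer handling of these kidneys before lysis stays open, since within groups the immediate early score correlated with the glycolysis and hypoxia score at 0.553 (exact permutation p = 0.157 over 9 libraries), and handling is confounded with group. An effect of the drug is open as well.

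Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, called as many genes. The real counts were 279, 59 and 637, and the highest of the other splits were 0, 3 and 0 for mutant against control, rapamycin against vehicle and treated mutant against control.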
